A study of Homo sapiens with 6 samples.

How the data were processed

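Gene expression was measured by sequencing of polyadenylated RNA in 6 libraries of HaCaT keratinocytes, 3 from control cells and 3 from FLG enhancer knockout cells. The authors deposited 1 table of estimated counts for the series, with 28202 rows named by gene symbol and values that need not be whole. Per the submitters' processing notes, fastp 1.0.1, kallisto 0.51.1 and DESeq2 1.50.2 were used with the hg38 build. The notes give no role or order for these tools. The gene annotation, the strand setting and any filter were not given in the sources used here. Estimated counts of this kind are shared out among overlapping or similar transcripts, which can move reads between genes with common sequence. A further 10 columns of the table matched no label of the 6 libraries and were not used here. Columns were assigned to libraries by name, and groups and replicate numbers were taken from the sample titles.

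Estimated counts were rounded to whole numbers. Totals per library ran from 11041175 to 18156488, and 25282 rows held a count above 0 in at least 1 of the libraries. Genes were kept by filterByExpr of edgeR with a minimum count of 10 and a minimum total of 15, which left 16841. Libraries were scaled by TMM factors, and knockout was compared with control in edgeR's quasi-likelihood framework (edgeR 4.0.16, R 4.3.3; glmQLFit and glmQLFTest, two-sided, group as the only term) with Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0259, a biological coefficient of variation of 16.1%. Standard errors are the absolute log2 fold change divided by the square root of F, and confidence intervals are at the 95% level. CPM values use the TMM-scaled library sizes. A floor of 3 counts over a group was used where its libraries were all at 0, and floors and intervals from counts cover counting error only. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so none was used for a p-value. The 10 splits of the libraries into 3 and 3 were refitted only to count the genes called. On simulated counts for the 16841 genes with 200 changed, the same fit called 68% of 2-fold and 83% of 3-fold changes, with 11 of 168 calls on unchanged genes. With so many calls the adjusted threshold is reached at a larger unadjusted p than in the real comparison, where 2 genes passed. The simulation also had no structure among the libraries besides the groups. These shares are therefore not the power of the real comparison. A simulated list shifted by 0.5 had a median of 0.50 and a camera adjusted p of 1.94e-22, and an unshifted list had 0.964. The simulated genes varied independently of each other. The simulation therefore cannot show how camera behaves for lists whose members vary together. In the real data the estimated correlation was 0.22 for interferon-stimulated genes and 0.39 for AP-1 genes.

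Gene lists for keratinocyte states, stress, signalling and other cell types, the tests, the alternatives below and the rule for named genes were chosen before the data were examined. Of 32 lists, 31 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists. The list of mitochondrially encoded genes had 0 rows in the table. Each list was also tested with camera at an estimated correlation and with fry, and by either of these 0 lists passed (lowest adjusted p 0.167 by camera). The lists share some genes, and the FLG family list lies within the epidermal differentiation complex. Under the rule for named genes, FLG is given first, then the genes with the largest changes among those past the threshold with a mean CPM of at least 5 and no overlap between groups. If fewer than 5 qualified, the 10 genes with the smallest p were to be given in their place, as was done here. Up to 4 members per list with the smallest p, every tested gene within 200 kb of FLG and the FLG family were added, and a subset of these is printed. IVL, PGLYRP3 and IFI6 were added after their values were seen. Some other genes outside the rule, such as LCE1E, SPRR1B and KPRP, are also printed.

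Gene positions came from a RefSeq table of GRCh38.p14, which placed 27656 rows, 533 of them through an older symbol, and 16580 of the genes tested. The exons of FLG, transcript lengths and shared sequence were taken from GENCODE v29 on GRCh38. Shared sequence was the percentage of distinct 31-mers of a gene's transcripts also found in transcripts of another gene. Transcript lengths were found for 93.2% of tested genes. Replicates of each group differed by more than sampling noise in every pair, so none appeared to be a library deposited again. That check does not show whether they came from separate cultures.

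Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma voom, no filter on low counts, a minimum mean CPM of 5, a replicate block, and each library left out in turn. Counts thinned to the smallest library, removal of a per-library trend with transcript length, and the complex and FLG family lists without FLG were added after seeing the data. Scripts ran in R and in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.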

Results

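Polyadenylated RNA was sequenced from HaCaT cells, a spontaneously immortalised line of human keratinocytes, in which an enhancer of the filaggrin gene FLG had been targeted with CRISPR-Cas9, and from control HaCaT cells. FLG encodes profilaggrin, the large precursor that is cut into filaggrin in the upper epidermis. Cas9 and guide RNAs were delivered by lentivirus, and transduced cells were selected with puromycin and expanded before RNA was taken. There were 3 control libraries and 3 enhancer knockout libraries, all with the same batch label, and the labels call them biological replicates without saying whether they came from separate infections. The p-values therefore measure the spread between these libraries. The estimated counts summed to 18156488, 17744323 and 16305840 in control replicates 1, 2 and 3, and to 11483143, 14253394 and 11041175 in knockout replicates 1, 2 and 3. The position and length of the targeted element were not given in the sources used here. The FLG level below therefore checks the labels only indirectly.

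The comparison of knockout with control cells asked how far expression of FLG, of its neighbours and of the rest of the transcriptome differed once the enhancer was targeted. FLG mRNA fell 2.90-fold in the enhancer knockout, from 541.8 ± 98.4 to 186.7 ± 27.3 CPM (normalised counts relative to library size; mean ± SD, n = 3 per group). The groups did not overlap. Control libraries held 595, 428 and 602 CPM of FLG, from 11171, 7801 and 9742 counts, and knockout libraries held 196, 156 and 208 CPM, from 2393, 2011 and 2247 counts. The log2 fold change was -1.54 ± 0.17 (SE; 95% CI -1.91 to -1.17; adjusted p = 0.00518, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). FLG lies on the minus strand of chromosome 1 at 152302165 to 152325239 (RefSeq, GRCh38). The GENCODE transcript has 3 exons, of which exon 3, at 152302175 to 152314747, makes up most of the 12747 nt of mRNA. With control replicate 1 left out the fold change was -1.48 and the call was lost (adjusted p = 0.152), although FLG still had the smallest p of all genes tested (8.95e-06). The fold change was -1.38 once a trend with transcript length between the libraries was removed.

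**Figure D1:**
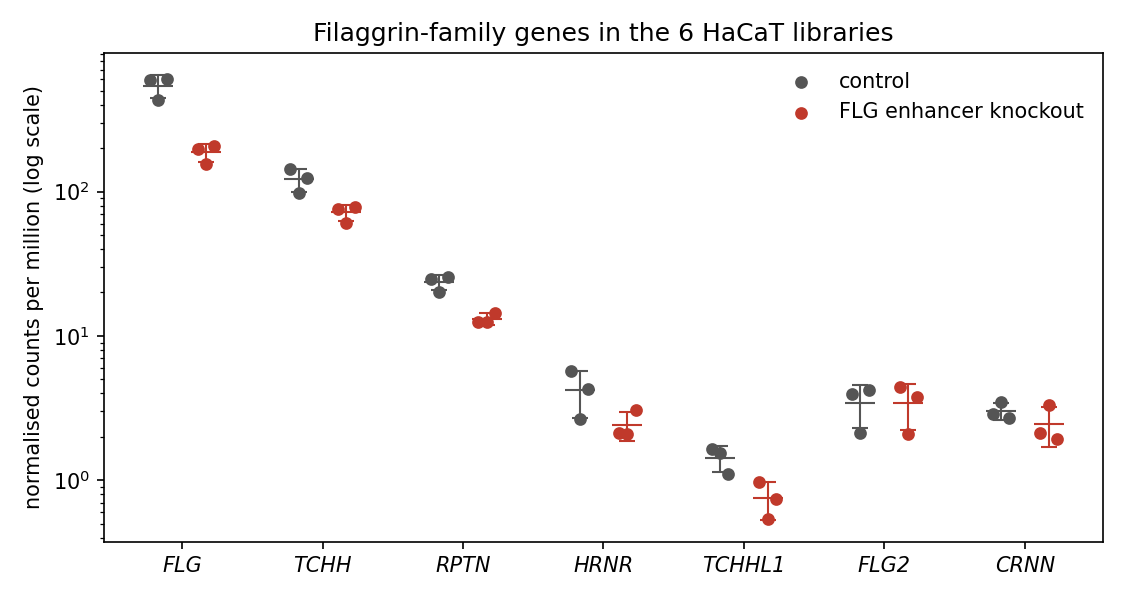
Normalised CPM (log axis) of the 7 tested S100-fused-type genes in each library, with controls in grey and enhancer knockouts in red. Dashes and bars give the mean ± SD of 3 libraries. FLG ran from 428 to 602 in controls and from 156 to 208 in knockouts, while FLG2, HRNR and CRNN had overlapping groups.

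Of 16841 genes tested across the genome, 2 were lower and 0 were higher in the knockout at an adjusted p of 0.05 by edgeR, and both had at least a 2-fold change. Unadjusted p-values under 0.05 were found for 407 higher and 297 lower genes, where chance alone gives 842 in both directions together. These counts depended on the libraries and the model used. They were 1183 and 1189 without knockout replicate 1, 198 and 118 without control replicate 1, and 515 and 492 with the replicate block. The main count therefore does not show that the rest of the transcriptome was unchanged. DESeq2 called 4 higher and 5 lower genes. Besides FLG, the gene called by edgeR was ZFP91-CNTF (chromosome 11, 58579114 to 58625733), a readthrough transcript of ZFP91 and CNTF, with 24, 46 and 37 counts in controls and 0 in every knockout library. Against a floor of 3 counts over the knockout group this was at least 24.1-fold lower, a bound that covers counting error only (adjusted p = 0.0446, edgeR). Most of its sequence also belongs to other genes, with 97.6% of its 31-mers found in their transcripts, so its estimated counts are uncertain. The call was lost without control replicate 1, control replicate 2 or knockout replicate 3 (adjusted p = 0.162, 0.232 and 0.0836).

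Among the other genes with the 10 smallest p-values, none passed in edgeR. CDRT4 had 34, 31 and 18 counts in controls and 0 in the knockouts, at least 18.7-fold lower against the same floor (adjusted p = 0.0618, edgeR), and 73.2% of its 31-mers also occur in other genes. SPDYE11 had 51 counts over the controls and 1 over the knockouts, and all of its 31-mers (100%) occur elsewhere. Higher values were measured for OASL, an interferon-induced oligoadenylate synthetase-like protein (21.1 ± 2.70 to 36.6 ± 3.15 CPM), for the hair keratin gene KRT81 (10.97 ± 0.377 to 19.3 ± 1.93 CPM), for TUBB3, a beta-tubulin gene (43.7 ± 1.98 to 66.1 ± 3.76 CPM), and for FST, which encodes the activin antagonist follistatin (43.7 ± 9.85 to 74.3 ± 7.52 CPM). Their adjusted p-values in edgeR were 0.35, 0.35, 0.43 and 0.43, and DESeq2 called all of these 4 genes higher. Without the low-count filter edgeR also called CDRT4, SPDYE11, OASL, KRT81 and FST. KRT81 shares 52.4% and TUBB3 shares 36.3% of its 31-mers with other genes.

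The next question was whether the genes around FLG differed as well. FLG sits in the epidermal differentiation complex, a cluster of genes for the cornified envelope and related proteins on chromosome 1, and 48 genes within 1 Mb of it were tested. FLG alone passed over all genes tested, and 3 passed when adjusted over the list alone (FLG, RPTN and TCHH; the same 3 in each of the 15 other settings of the fit). TCHH, which encodes trichohyalin, a structural protein of the hair follicle, was at 121.9 ± 22.6 CPM in controls and 71.8 ± 9.61 CPM in knockouts (log2 fold change -0.76 ± 0.16; adjusted p = 0.43 over all genes and 0.00378 over the list, edgeR). RPTN, which encodes the cornified-envelope protein repetin, was at 23.5 ± 2.88 and 13.2 ± 1.19 CPM (log2 fold change -0.84 ± 0.16; adjusted p = 0.35 and 0.00275). DESeq2 and edgeR without the low-count filter called both over all genes. Both genes lie at lower coordinates than FLG, TCHH at 152106317 to 152115444 and RPTN at 152153595 to 152159228. Neither shares any 31-mer with FLG (0%), and with the transcript length trend removed their fold changes were -0.68 and -0.85. None (0) of the 22 tested genes at higher coordinates passed over the list by edgeR. Among those, PGLYRP3 was at -0.36 (unadjusted p = 0.0468, edgeR). LCE1E was at 0.16 ± 0.15 and SPRR1B at -0.12 ± 0.17. Other genes on that side had few counts and wide errors, such as CRCT1 (0.888 CPM in controls, SE 0.54) and KPRP (0.917 CPM, SE 0.51). A fall as large as that of TCHH could go unseen in such genes. HRNR, at lower coordinates, did not pass at -0.80 either (4.22 CPM in controls, SE 0.34). IVL, the abundant involucrin gene, was at 1546 ± 212 CPM in controls and 1422 ± 173 CPM in knockouts.

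**Figure D2:**
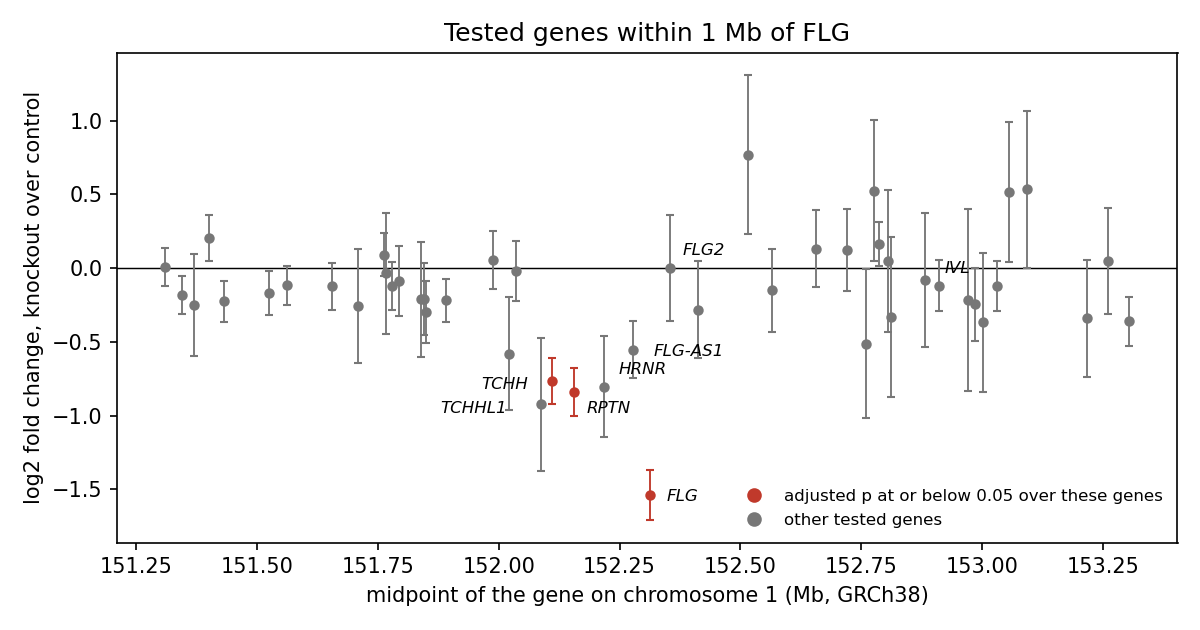
Log2 fold change of the enhancer knockout over control (± SE of the fit) against the midpoint of each of the 48 tested genes within 1 Mb of FLG. Red points are FLG, TCHH and RPTN, at -1.54, -0.76 and -0.84, which passed when adjusted over these genes alone; grey points are the other genes.

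The 7 tested S100-fused-type genes, the family of FLG, were lower as a group, with 6 of 7 at lower levels and a median log2 fold change of -0.80 (camera adjusted p = 6.12e-15 with a preset correlation of 0.01; adjusted p = 0.167 with an estimated correlation). FLG passed over all genes, and FLG, RPTN and TCHH passed when adjusted over the list alone. HRNR, the hornerin gene, was at -0.80 ± 0.34 (4.22 ± 1.54 to 2.43 ± 0.544 CPM), TCHHL1 at -0.92 ± 0.45 (1.43 ± 0.284 to 0.756 ± 0.221 CPM) and CRNN, the cornulin gene, at -0.28 ± 0.33. For HRNR and for CRNN the control and knockout libraries overlapped. FLG2, whose nearer end lies 23.5 kb from FLG, was at 3.43 ± 1.12 CPM in controls and 3.44 ± 1.21 CPM in knockouts, with a confidence interval of -0.76 to 0.77 on the log2 scale and a sign that turned with library size alone, without a low-count filter, in limma voom and with some libraries left out. The antisense transcript FLG-AS1 overlaps FLG and was at -0.55 ± 0.19 (13.4 ± 2.84 to 9.15 ± 0.533 CPM; adjusted p = 0.919). Of its 31-mers, 8.44% also occur in FLG, and reads from that part are uncertain, since strand use in the counting was not given in the sources used here. Without FLG the list had a median of -0.78 (camera adjusted p = 2.74e-07; adjusted p = 0.355 with an estimated correlation).

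The epidermal differentiation complex as a whole had 27 of 43 tested genes lower, a median log2 fold change of -0.12 and a camera adjusted p of 0.00124 (adjusted p = 0.686 with an estimated correlation). FLG was the 1 member past the threshold over all genes, and FLG, RPTN and TCHH were the 3 adjusted over the list alone. S100A3 was higher at 0.94 ± 0.30 (2.30 ± 0.365 to 4.43 ± 0.916 CPM) and did not pass. This list lost its call without control replicate 3 (adjusted p = 0.0866) and without knockout replicate 1 (adjusted p = 0.786), where the median was -0.02. Without knockout replicate 2 the median was -0.27 (adjusted p = 2.29e-12), and with the length trend removed it was -0.21 (adjusted p = 3.29e-08). Without FLG the list had a median of -0.11 (adjusted p = 0.0322; adjusted p = 0.686 with an estimated correlation).

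Lists of keratinocyte differentiation genes outside the complex did not pass in the main test. Granular and cornified-layer genes had a median log2 fold change of 0.04 over 24 tested members (camera adjusted p = 0.314), which ran from -0.04 without knockout replicate 3 to 0.15 without knockout replicate 1. In that list 1 member passed when adjusted over the list alone, SPINK5, which encodes a serine protease inhibitor of the epidermis. It was at 52.4 ± 8.48 CPM in controls and 87.3 ± 23.1 CPM in knockouts. Over all genes its adjusted p was 0.919 by edgeR, 0.00323 by edgeR without the low-count filter and 0.168 by DESeq2. SPINK5 was also the 1 gene adjusted over the list alone among 16 genes of profilaggrin processing and filaggrin breakdown (median 0.05, camera adjusted p = 0.192). Spinous genes had a median of 0.00 with 7 of 15 higher (adjusted p = 0.81), and the suprabasal keratin KRT1 was at 422 ± 3.53 and 365.9 ± 30.0 CPM. Basal and hemidesmosome genes had a median of -0.11 (15 of 21 lower; adjusted p = 0.314). Medians were -0.05 for junction genes, 0.07 for barrier lipid genes, -0.06 for differentiation transcription factors and -0.03 for stress keratins (adjusted p = 0.395, 0.515, 0.259 and 0.395). With each library left out, medians ran from -0.05 to 0.03 for spinous genes, -0.01 to 0.10 for barrier lipid genes and -0.05 to 0.13 for stress keratins. With 1 library left out, calls appeared for profilaggrin processing without control replicate 1 (median 0.09, adjusted p = 0.0362), for basal genes and differentiation transcription factors without control replicate 2 (medians -0.15 and -0.09, adjusted p = 0.0264 for each), and for junction genes without knockout replicate 3 (median -0.11, adjusted p = 0.0481). Without knockout replicate 2 the basal and junction medians turned to 0.01 and 0.04 (adjusted p = 0.935 and 0.545), and that of differentiation transcription factors was -0.01. The median of profilaggrin processing turned to -0.01 without control replicate 2. Without knockout replicate 1 medians were -0.17 for basal genes, -0.14 for differentiation transcription factors, -0.13 for junction genes and 0.11 for profilaggrin processing. With the length trend removed the basal median was -0.01. KLF4, a transcription factor of the upper epidermis, was at 108.9 ± 15.2 and 80.0 ± 12.5 CPM (adjusted p = 0.919). The camera direction of the spinous and stress keratin lists was upward although their medians were below 0.

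Interferon-stimulated genes were higher as a group in the knockout, with 33 of 37 tested members higher and a median log2 fold change of 0.31 (camera adjusted p = 6.12e-15; adjusted p = 0.502 with an estimated correlation). None (0) passed over all genes in edgeR, 14 had an unadjusted p under 0.05, all higher, and 2 passed when adjusted over the list alone, OASL and IFI44. DESeq2 called OASL over all genes and no other member. Without the low-count filter edgeR called 6 members, among them OASL, IFI44, IFI27, IFI6 and ISG15 (adjusted p = 0.0442 for ISG15). The adjusted p-values by DESeq2 were 0.0684 for IFI44, 0.743 for IFI27, 0.995 for IFI6 and 0.961 for ISG15. IFI44 was at 11.5 ± 2.40 CPM in controls and 20.6 ± 2.51 CPM in knockouts. ISG15, a ubiquitin-like modifier, was at 25.8 ± 3.94 and 40.9 ± 12.3 CPM, and IFI27 at 11.7 ± 5.35 and 22.4 ± 7.17 CPM. The mean centred log2 CPM of the list was 0.08, -0.35 and -0.26 in control replicates 1, 2 and 3 and 0.13, 0.18 and 0.22 in the knockouts, so that control replicate 1 lay close to the knockout libraries. Antigen presentation genes had a median of 0.10 (12 of 19 higher; camera adjusted p = 0.551), and cytokine, chemokine and alarmin genes a median of 0.09 (18 of 24 higher; adjusted p = 0.124), among them CXCL8 at 24.7 ± 7.59 and 36.0 ± 4.01 CPM. The cytokine list passed without control replicate 2, knockout replicate 1 or knockout replicate 3 (adjusted p = 0.023, 0.00408 and 0.0425), and antigen presentation without knockout replicate 1 (adjusted p = 0.0492). The cytokine median was 0.23 without knockout replicate 1, 0.04 without knockout replicate 2 (adjusted p = 0.977) and 0.00 with the length trend removed. The antigen presentation median was -0.02 without control replicate 2 or knockout replicate 2 and 0.00 without knockout replicate 3.

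AP-1 and immediate early transcription factor genes were lower as a group, with 10 of 14 lower and a median log2 fold change of -0.23 (camera adjusted p = 3.83e-06; adjusted p = 0.686 with an estimated correlation). None (0) passed over all genes in edgeR or DESeq2, 5 had an unadjusted p under 0.05, and 4 passed when adjusted over the list alone, ATF3, FOSB, FOS and EGR1. Without the low-count filter edgeR called 2 of them over all genes, ATF3 (adjusted p = 0.00554) and FOSB (adjusted p = 0.0288). ATF3 was at 56.9 ± 11.2 CPM in controls and 35.1 ± 3.37 CPM in knockouts, FOS at 729.4 ± 84.0 and 515.6 ± 24.3 CPM, FOSB at 245.3 ± 60.5 and 159.2 ± 18.9 CPM, and EGR1 at 554.7 ± 88.5 and 392.7 ± 61.1 CPM. The groups overlapped on the list as a whole, with a mean centred log2 CPM of 0.32, -0.06 and 0.19 in control replicates 1, 2 and 3 and -0.01, -0.15 and -0.29 in the knockouts.

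Cell-cycle and proliferation genes were higher as a group, with 31 of 36 higher and a median of 0.19 (camera adjusted p = 9.9e-09; adjusted p = 0.686 with an estimated correlation). None (0) passed over all genes in edgeR or DESeq2 or when adjusted over the list alone, and 6 had an unadjusted p under 0.05. The replication genes MCM5 and GINS2 were at 40.4 ± 6.76 and 23.8 ± 5.35 CPM in controls and at 54.5 ± 0.879 and 34.1 ± 3.58 CPM in knockouts. The mean centred log2 CPM of the list was -0.24, 0.06 and -0.10 in control replicates 1, 2 and 3 and 0.10, 0.07 and 0.11 in the knockouts, so that control replicate 2 lay level with knockout replicate 2. The median was 0.11 without control replicate 1.

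Unfolded protein and integrated stress response genes (20 of 23 higher, median 0.13) and simple-epithelium keratins (7 of 9 higher, median 0.18) were also higher as groups, with camera adjusted p-values of 0.00393 and 0.0201 and an adjusted p of 0.686 for each with an estimated correlation. No member (0) of either passed over all genes in edgeR or DESeq2 or adjusted over the list alone. Of the keratins, KRT18 was at 222.1 ± 9.81 and 313 ± 61.5 CPM and KRT8 at 1344 ± 108 and 1741 ± 277 CPM, and 35% and 25.3% of their 31-mers occur in other genes. Both group calls were lost without knockout replicate 2 (adjusted p = 0.0522 and 0.131) and with the length trend removed (adjusted p = 0.081 and 0.0939). The stress response median was then 0.10 and 0.09, and the keratin median 0.04 in both settings. The keratin list also lost its call without control replicate 2, control replicate 3 or knockout replicate 3 (adjusted p = 0.11, 0.0624 and 0.151). Its median was 0.12 without control replicate 2, 0.04 without control replicate 3 and 0.30 without knockout replicate 1.

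**Figure D3:**
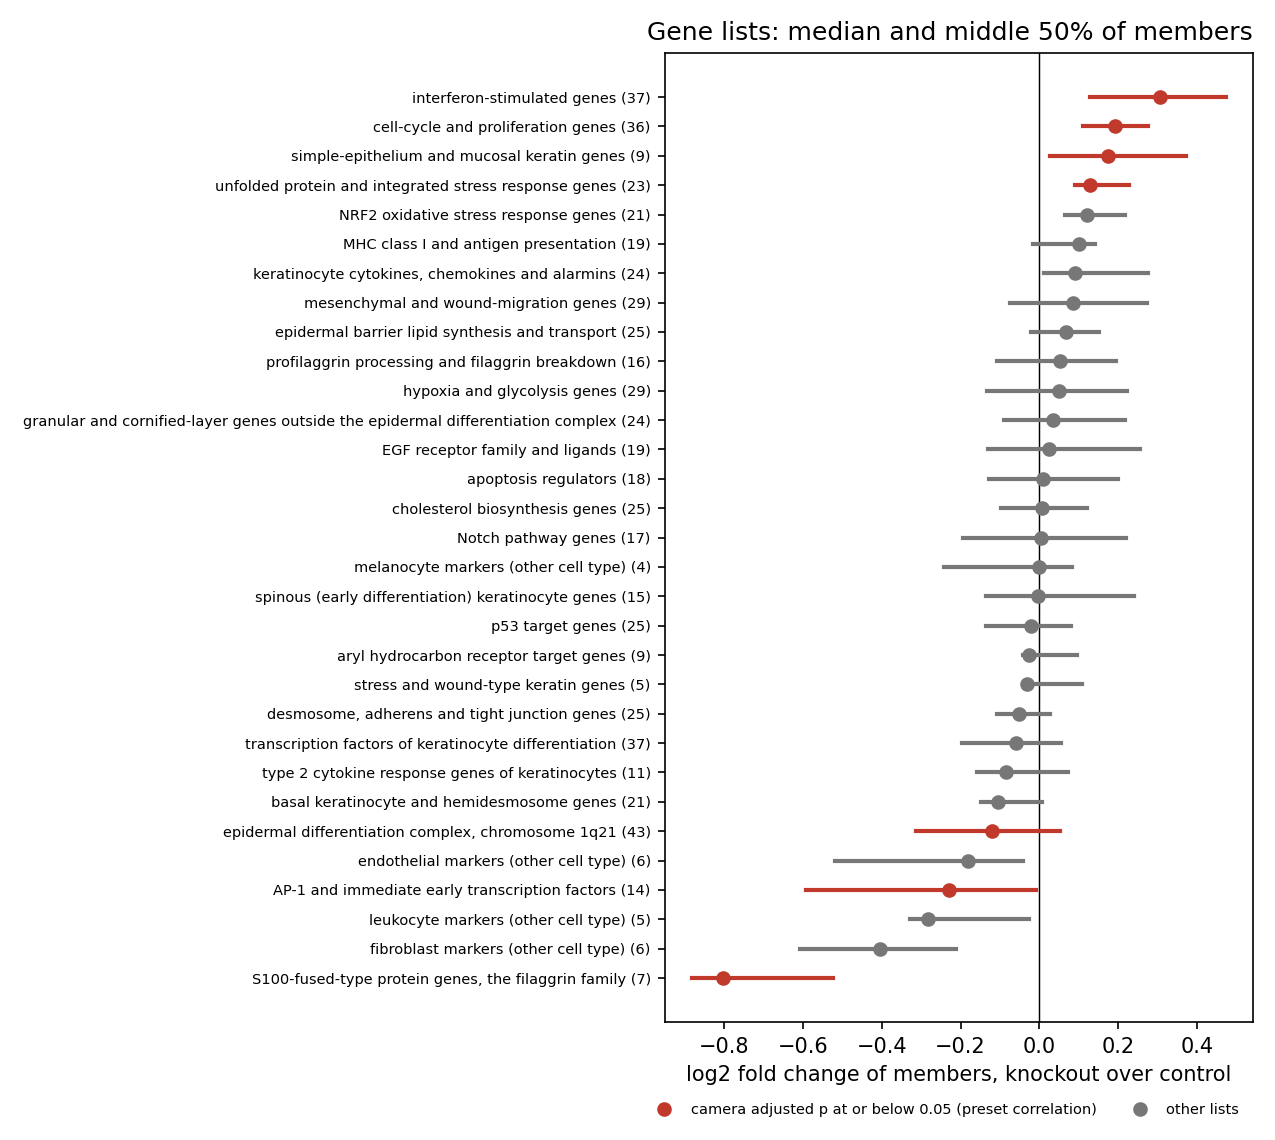
Median (points) and middle 50% (bars) of the log2 fold change, enhancer knockout over control, of the tested members of 31 gene lists, with the number tested in brackets. Red marks the 7 lists with a camera adjusted p at or below 0.05 at a preset correlation, from the S100-fused-type genes at -0.80 to the interferon-stimulated genes at 0.31; with an estimated correlation 0 of them passed.

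The other lists did not pass in the main test. Type 2 cytokine response genes had a median of -0.09 over 11 tested genes (camera adjusted p = 0.901, direction upward), with SOCS1, a feedback inhibitor of cytokine signalling, the 1 gene past when adjusted over the list alone (14 counts over the controls and 44 over the knockouts; 0.262 ± 0.0517 and 1.21 ± 0.452 CPM; adjusted p = 0.919 over all genes). NRF2 response genes had 17 of 21 higher and a median of 0.12 (adjusted p = 0.105; 0.0438 without control replicate 2, 0.336 with a median of 0.03 without control replicate 1, and 0.0268 at a mean CPM of at least 5), and mesenchymal and wound-migration genes a median of 0.09 over 29 (adjusted p = 0.205). Medians lay at -0.02 for p53 targets, -0.03 for aryl hydrocarbon receptor targets, 0.01 for cholesterol synthesis and 0.05 for hypoxia and glycolysis (adjusted p = 0.912, 0.752, 0.515 and 0.66). They were 0.01 for apoptosis regulators, 0.00 for Notch pathway genes and 0.03 for EGF receptor ligands (adjusted p = 0.53, 0.81 and 0.395). With each library left out, the medians of these 7 lists stayed between -0.09 and 0.13, with all but hypoxia on both sides of 0, and that of mesenchymal genes ran from 0.01 to 0.09. The direction of the aryl hydrocarbon receptor list was upward despite its median, and the Notch list had a mean of -0.03. Markers of other cell types did not pass either. Fibroblast markers had a median of -0.40 over 6 tested genes, leukocyte markers -0.28 over 5, endothelial markers -0.18 over 6 and melanocyte markers 0.00 over 4 (adjusted p = 0.193, 0.395, 0.395 and 0.515). With each library left out these medians ran from -0.67 to -0.21, -0.47 to -0.10, -0.33 to -0.04 and -0.19 to 0.08.

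The libraries also differed in ways that moved partly with the groups. Each control library had more counts than each knockout library. Ribosomal RNA genes took 0.752, 0.979 and 0.843% of counts in control replicates 1, 2 and 3 and 0.717, 2.03 and 0.695% in knockout replicates 1, 2 and 3. Ribosomal protein genes took 5.87, 7.06 and 6.87% against 5.63, 9.38 and 7.17%. The first principal component, with 37.4% of the variance, placed the controls at -22.7, -24.4 and 7.52 and the knockouts at -26.5, 41.5 and 24.6. Spearman's rho of expression relative to the mean library with transcript length, across genes, was 0.171, 0.084 and 0.181 in the controls and 0.316, -0.476 and -0.043 in the knockouts, and the fold changes themselves had a rho of -0.295 with length (15694 genes, which are not independent replicates). With that trend removed, median log2 fold changes were -0.68 for the FLG family, 0.25 for interferon-stimulated genes, 0.15 for proliferation genes and -0.27 for AP-1 genes. Without knockout replicate 2, the library farthest out on the first component, these medians were -0.70, 0.28, 0.18 and -0.24, and edgeR called 3 genes, FLG and ZFP91-CNTF among them.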

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

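FLG was lower under all 15 other settings of the fit, with log2 fold changes from -1.69 to -1.38 and adjusted p-values from 9.26e-16 to 0.152, and 14 of these passed. Leaving out each library in turn gave -1.69 to -1.42, and the call was lost only without control replicate 1 (-1.48). Genes within 1 Mb adjusted over the list alone were the same 3 throughout. The cause of the following differences was not tested. Genes lower numbered 1 with library size alone, 5 by DESeq2, 17 without a low-count filter, 1 at a mean CPM of at least 5, 1 with thinned counts and 0 to 3 with a library left out. Genes higher numbered 4 by DESeq2, 25 without the filter and 0 to 1 with a library left out. Calls with at least a 2-fold change numbered 1 with library size alone, 23 without the filter, 1 at a mean CPM of at least 5, 1 with thinned counts and 0 to 4 with a library left out. In all, 2 genes were called in the main comparison, 9 by DESeq2 and 42 without the filter. For FLG, edgeR without the filter gave an unadjusted p of 3.37e-19 against 3.08e-07 in the main comparison. The log2 fold change barely moved (-1.55 against -1.54). Called genes within 1 Mb of FLG numbered 3 by DESeq2, 3 without the filter and 0 to 1 with a library left out. ZFP91-CNTF no longer passed in 5 settings, and CDRT4 passed in 6.

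The epidermal differentiation complex had an adjusted p of 0.0636 without the filter, 0.686 with an estimated correlation, 0.52 by fry and 2.29e-12 to 0.786 with a library left out. Of the other lists, 0 passed with an estimated correlation and 0 by fry, against 6 in the main test and 4 to 9 with a library left out. FLG2, at 0.00 in the main comparison, turned to -0.0291 with library size alone, -0.0061 by limma voom, -0.0124 without the filter and -0.000166 with the replicate block, and ran from -0.25 to 0.27 with a library left out. It had 1.12 CPM of spread between controls, so its sign carries no information at this depth. Over the 39 genes recomputed in every setting that tested them, 567 of 574 values outside the main comparison had the same sign as in it, and the 7 that turned were those of FLG2. Many of these genes were named for a small p in the main comparison, and the settings reuse the same libraries. Agreement in sign was therefore largely built in.

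Whether replicate numbers pair the samples was not decided. Deviations of same-numbered libraries had correlations of 0.145, -0.034 and 0.253, the last being the highest of any control and knockout pair. Those of differently numbered libraries ran from -0.332 to 0.233, and control replicate 2 correlated best with knockout replicate 1 (0.233). With the replicate block 2 genes were called, as without it. FLG then had an adjusted p of 7.13e-05, against 0.00518 in the main edgeR comparison.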

Other observations

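The tests of a wider fall of late differentiation genes and of place beside FLG were chosen after the results were seen, as were the thinned counts, the length correction and the lists without FLG.

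TCHH and RPTN, at log2 fold changes of -0.76 and -0.84, lay below 0 beside FLG. Reads shared with FLG are argued against, since 0% of the 31-mers of either gene occur in FLG. A trend with transcript length leaves at least 89.4% of each change in place once removed. A wider fall of late keratinocyte differentiation genes was taken to bring the granular list to -0.38 or below, a bound set for the test. Its median was 0.0358, with 0 of 24 members as low as TCHH. The bootstrap 95% interval of -0.05 to 0.13 resampled the genes of the list, so it leaves out the spread between libraries. With each library left out the median ran from -0.04 to 0.15, above that bound throughout. An effect of the enhancer knockout that depends on place beside FLG remains a hypothesis that may hold but is undecided: the 6 tested genes nearest to FLG, leaving out TCHH and RPTN, which define the pattern, and FLG-AS1, which overlaps FLG, had a mean log2 fold change of -0.23, and 6% of 16445 runs of 6 neighbouring genes were as low (3% of 15221 runs among genes at 1 CPM or more), short of the lowest 1% set for the test. Those 6 genes had few counts, with SE from 0.28 (LCE3E) to 0.54 (CRCT1), and the runs were not matched for this. The shares therefore do not allow for the noise of such genes. With only FLG left out the mean was -0.54 and 0.25% of runs were as low, but the 6 genes then include the pattern itself.

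ZFP91-CNTF and CDRT4 were at 0 counts in all knockout libraries. A candidate explanation is that estimated counts were shared out differently among overlapping genes, and at least 73.2% of the 31-mers of each occur in other genes. TVP23C-CDRT4 is the readthrough that shares 72.7% of the 31-mers of CDRT4. It was at 10.3, 8.27 and 8.87 CPM (by library total) in controls and 13.77, 9.26 and 10.98 in knockouts. On this scale the groups overlapped only through control replicate 1 and knockout replicate 2. The TMM factors of these libraries were 1.0353 and 0.9061, and with TMM scaling the knockouts lay above the controls without overlap. TVP23C was lower without overlap (9.27, 9.06 and 7.38 against 7.2, 4.4 and 6.17). The readthrough could hold reads of CDRT4, but with TVP23C lower as well these levels do not settle where they would have gone. ZFP91, at 115.2, 127.5 and 122 against 143, 84.6 and 122.2, varied too much to show it for ZFP91-CNTF, so sharing is not decided by them. Other genes with joined names of the readthrough type were called in some fits. DNAAF4-CCPG1 was called without knockout replicate 2 and ZNF765-ZNF761 without knockout replicate 1. Both were called without the low-count filter, as was IPO11-LRRC70. The shared sequence of these genes was not measured. A change in ZFP91-CNTF or CDRT4 RNA itself stays open, as it was not tested.

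Interferon-stimulated genes were higher in the knockout as a list. A single library as the cause is argued against by the medians with each library left out, which kept at least 79.6% of the value (0.24 to 0.42). A trend with transcript length is argued against by the 82.8% of the median that stayed once it was removed. The call does not survive an estimated correlation among the genes (adjusted p = 0.502), so a shared fluctuation of these genes between cultures may account for it. The control construct was not given in the sources used here. It is therefore unknown whether guide RNAs, infection and selection were matched between the groups. Effects of these steps cannot be told apart here from those of the enhancer knockout, and no biological explanation was tested.

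The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of these splits, 2 gave as many genes as the real one, itself included, with 2 genes in the real split and 141 in the highest other. That other split sets control replicates 1 and 2 with knockout replicate 1 against the remaining libraries, the sides that the first principal component separates, and it points to a structure of the samples besides the groups.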
